A study of Mus musculus with 12 samples.

How the data were processed

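RNA sequencing of mouse aorta was analysed in 12 libraries, 4 for each of 3 groups (NFD, HFD and HFD+TUDCA), grouped by the sample titles. Poly(A) RNA was extracted with Trizol, selected with oligo(dT) and made into NEBNext Ultra libraries, per the labels' protocols. Reads were assigned on the build GRCm38, per the submitters' processing notes, which also name DESeq2. The aligner, the counting program and the annotation release are not given in the sources used here. Per the file headers, the authors deposited 1 count and 1 FPKM value (fragments-per-kilobase-per-million) for each of 22183 genes and 12 libraries. The deposited counts are taken to be expected counts, because 8.53% to 9.43% of the values of a library were not whole numbers, and they were rounded before the count tests. The gene lengths behind the deposited FPKM values are not given in the sources used here. Symbols and pathways came from the deposited annotation, with 13 genes lacking a symbol and 9190 genes having a pathway. Coordinates are those of GENCODE M21 on GRCm38, matched by identifier for 22128 genes, and the named genes given with coordinates are annotated as protein-coding.

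Counts of genes whose reads can be shared are uncertain, since the counting could divide reads between near copies. This holds for the major urinary protein genes, Lilrb4a and Lilrb4b, Hspa1a and Hspa1b, the globin genes, and Cldn22, which overlaps Wwc2. Poly(A) selection limits the measurement to polyadenylated RNA, and FPKM values divide by a gene length that the counts do not need.

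The main test was the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3, robust fit) with TMM scaling on the 2 groups compared, after filterByExpr with a minimum count of 10 and a minimum total of 15. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed, and those with a fold change of at least 2 were counted as well. The SE of a log2 fold change was its size divided by the square root of F. CPM (counts-per-million) used the TMM factors of all 12 libraries (0.895 to 1.08), and log2 CPM a prior count of 2. Where all libraries of a group had 0 counts, the fold was bounded with a floor of 3 counts over the group. Floors cover counting error only.

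The 38 gene lists were fixed before the data were examined, as was the rule for named genes. A list needed 3 measured members and was tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Alternatives were an estimated correlation, fry, which tests whether the genes of a list move 1 way on balance, and an exact permutation test of list scores. Some genes belong to more than 1 list, such as Mmp12, Ctsk, Ctss and Cd74. The list members Mx1, Atp5f1a, Atp5f1b, Atp5po and Xist had no matching symbol in the table used. Pathways with 10 to 300 tested members were tested with Fisher's exact test, one-sided, against 6428 tested genes with a pathway in HFD vs NFD.

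By the rule for named genes, each comparison names the 10 called genes with the largest rise and the 10 with the largest fall that had a mean of at least 1 CPM and no overlap between the groups, without predicted genes and without immunoglobulin and T cell receptor segments. With none called, the 5 genes with the lowest unadjusted p in each direction were taken. Up to 4 members of each list with the smallest unadjusted p and a fixed panel (Apoe, Hspa5, Ddit3, Atf4, Xbp1, Il1b, Ccl2, Vcam1, Icam1, Cd68, Trem2, Mmp12, Acta2, Myh11, Col1a1, Abca1, Gpbar1 and Nr1h4) were added, and some genes that the rule names are not reported here. Gpbar1 was below the count filter and was not tested. Genes of other tissues (Krt4, Scgb1a1, Cyp11b1, Star) were chosen after their values were seen, and a gene named in 1 comparison is also given in others.

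Alternatives covered RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, limma-trend on log2(FPKM + 1), other filters and thresholds, 1 fit of all 12 libraries, the replicate number as a block, and each library left out in turn. In data simulated from the HFD vs NFD means (14789 genes), edgeR recovered 81.8% of genes changed 4-fold, 19.4% of those changed 2-fold and 1.49% of those changed 1.5-fold, and 2.60% of its calls were false. For HFD+TUDCA vs NFD (14778 genes) it recovered 83.3%, 18.2% and 1.52%, with 5.06% of calls false. For HFD+TUDCA vs HFD (14454 genes) it recovered 60.9%, 2.99% and 0%, with 2.38% of calls false. DESeq2 had 24.4%, 30.9% and 29.8% false calls in the same simulations. These drew each gene independently from the dispersions of edgeR, in 1 draw per comparison. The setting may favour edgeR, and the rates are not those of DESeq2 in the real data. Tables were handled with data.table (1.17.8), pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15, and figures drawn with matplotlib 3.10.9.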

Results

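Gene expression was measured by RNA sequencing of the aorta, from its ascending part to its bifurcation, in male mice that lack apolipoprotein E. These mice clear lipoproteins poorly and develop atherosclerotic lesions. The 12 libraries fell into 3 groups of 4. The NFD group received a normal diet with 5% fat and no added cholesterol, and the HFD group a high-fat diet with 16% fat and 0.25% cholesterol. The HFD+TUDCA group received the high-fat diet and, after 8 weeks of it, 1000 mg/kg of tauroursodeoxycholic acid (TUDCA) per day by gavage for 4 weeks, while the other groups received saline. TUDCA is a taurine-conjugated bile acid that is used as a chemical chaperone against stress of the endoplasmic reticulum (ER). Total counts ranged from 15199317 to 22061692 per library, and 16532 to 17121 genes had at least 1 count. A count of 0 allowed a level of up to 0.136 to 0.197 CPM (counts-per-million), depending on the library, for counting error only. Unless another error is named, ± after a level is the SD over the 4 libraries of a group and ± after a log2 fold change is its SE.

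Apoe, the targeted gene (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188, minus strand), had 184 to 641 counts in each of the 12 libraries, or 11.2 to 34.1 CPM. The level of Apoe was 13.9 ± 3.13 CPM in NFD, 19.0 ± 3.48 CPM in HFD and 19.1 ± 10.1 CPM in HFD+TUDCA, and no comparison passed the test. A count per gene does not show which exons the reads came from, so these levels do not check the genotype. Correlations of log2 CPM between libraries of 1 group ranged from 0.855 to 0.981. The first principal component held 33.9% of the variance and the second 22.8%, and HFD replicates 1 and 4 and HFD+TUDCA replicate 4 lay farthest from the other libraries. The share of counts from mitochondrial genes ranged from 8.56% in HFD replicate 4 to 19.2% in HFD+TUDCA replicate 4.

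The comparison of HFD with NFD asked what the high-fat diet changed in the aorta. Genes of lipid-laden macrophages, neutrophils, cytokines and matrix-degrading enzymes were higher on the high-fat diet, and genes of cholesterol synthesis, fatty acid synthesis and heart muscle were lower. With an estimated correlation between genes the lists of foam cells (adjusted p = 0.0318) and matrix proteases (0.0319) kept their call, and those of neutrophils (0.0873), cytokines (0.0895), cholesterol synthesis (0.164), heart muscle (0.164) and fatty acid synthesis (0.351) lost it. Gpnmb, a membrane glycoprotein of lipid-laden macrophages, rose 45.8-fold, from 17.2 ± 2.88 to 789 ± 425 CPM. Mmp12, which encodes macrophage elastase, rose 57.0-fold, from 1.79 ± 0.26 to 102 ± 42.0 CPM, and had the lowest adjusted p of the comparison (log2 fold change 5.83 ± 0.33, edgeR adjusted p = 1.73e-04). The chaperone gene Hspa5, which encodes the ER protein BiP, rose 1.98-fold, from 210 ± 31.6 to 414 ± 93.4 CPM. Among the genes that fell were Nsdhl, an enzyme of cholesterol synthesis, which was 2.24-fold lower at 18.3 ± 1.70 against 41.2 ± 6.17 CPM, and Myh6, the alpha myosin heavy chain of heart muscle, which was 4.75-fold lower at 297 ± 203 against 1413 ± 621 CPM. The call of Myh6 was kept in 2 of the 8 fits that left out 1 library (log2 fold change -2.84 to -1.97, adjusted p up to 0.121).

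Of 14918 genes tested with edgeR, 720 changed, 475 of them higher and 245 lower in HFD, and 532 of these changed at least 2-fold (346 higher and 186 lower). With upper-quartile scaling in place of TMM the split was 407 higher and 332 lower. The majority turned with limma-trend, to 320 higher and 408 lower on log2(FPKM + 1) and 344 higher and 392 lower on log2(FPKM + 0.1). At an unadjusted p under 0.05 there were 3126 genes. The HFD and NFD libraries did not overlap in 2209 genes (14.8% of those tested, where the average over all splits of the 8 libraries is 2.86%). Genes are correlated, so a single split can lie far from that average. The number of changed genes depended on single libraries, with 188 without NFD replicate 1, 363 without NFD replicate 2, 178 without NFD replicate 3, 282 without NFD replicate 4, 473 without HFD replicate 1 and 1181 without HFD replicate 3. DESeq2 called 1686 genes, and in alternatives added after the data were seen 377 passed with the score of the heart muscle list as a covariate and 88 with that of the mesothelial and epithelial list. Of 51 named genes called here, 28 kept their call in all 8 fits that left out 1 library, while Cnn1 kept it in 1, Myh6 and Igkc in 2, Csf3, Vcam1, Acly, Ighm and Cyp1a1 in 3, and Apoa1, Hspa5 and Abca1 in 4. Nothing in the labels states that each library came from a separate animal, so the p-values here measure only the spread between these samples.

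Of the 10 genes with the largest rise, Spp1 (osteopontin) went from 6.52 ± 0.64 to 815 ± 669 CPM (log2 fold change 6.98 ± 0.74, edgeR adjusted p = 0.00216), and Saa3, an acute-phase serum amyloid, from 3.33 ± 1.55 to 184 ± 206 CPM (5.82 ± 0.85, adjusted p = 0.00922). The cytokine Il6 (8.41 ± 1.35), the granulocyte growth factor Csf3 (9.33 ± 1.92), the neutrophil chemokine Cxcl1 (5.95 ± 1.01), the pattern recognition molecule Ptx3 (6.34 ± 0.88) and Acod1, the enzyme that makes itaconate (7.20 ± 1.17), rose from levels of 0.0377 to 1.57 CPM. Without 1 library the log2 fold change ranged from 6.65 to 11.998 for Csf3, which kept its call in 3 of 8 fits, from 6.84 to 11.10 for Il6 (5 of 8) and from 4.59 to 6.55 for Cxcl1 (6 of 8). Lilrb4a, an inhibitory leukocyte receptor, had no count in any NFD library and was at least 149-fold higher in HFD against a floor of 3 counts over the group. Its counts are uncertain, because the neighbouring Lilrb4b is a near copy. The 10 largest falls included 5 genes of the major urinary protein family, led by Mup7 (log2 fold change -6.77 ± 0.88), whose near-identical copies can share reads. The liver apolipoprotein gene Apoa1 was 23.5-fold lower, from 2.36 ± 1.78 to 0.0985 ± 0.160 CPM, and Serpina3b, a serine protease inhibitor, fell 19.8-fold from 43.4 ± 9.26 to 2.18 ± 1.59 CPM. The liver gene Alb (albumin), chosen after its values were seen, stood at 36.6, 7.08, 12.2 and 5.10 CPM in NFD replicates 1 to 4, at 0.245 to 3.21 CPM in HFD and at 1.43 to 40.7 CPM in HFD+TUDCA, so unequal traces of liver RNA were not excluded as a cause of the falls of Apoa1 and the Mup genes. Col10a1, a cartilage collagen, and Nppb, a natriuretic peptide of the heart, fell 27.3-fold and 22.1-fold. Without 1 library the log2 fold change ranged from -6.48 to -3.87 for Apoa1, which kept its call in 4 of 8 fits, and from -6.20 to -4.14 for Nppb (5 of 8). Cldn22 had 0 counts in all 4 HFD libraries and was at least 123-fold lower over the group, but its counts were not whole numbers in NFD and neither were those of the overlapping gene Wwc2 there, while Wwc2 had whole counts in all 8 libraries on the high-fat diet, so that the assignment is uncertain in comparisons with NFD. Genes with counts that were not whole in all libraries of 1 group and whole in the other 8 numbered 4 for NFD, 2 for HFD and 0 for HFD+TUDCA. Other sets of 4 libraries had 0.346 such genes on average and up to 6. NFD lay above that average and below the highest set, so this count does not settle whether NFD was counted differently.

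**Figure D1:**
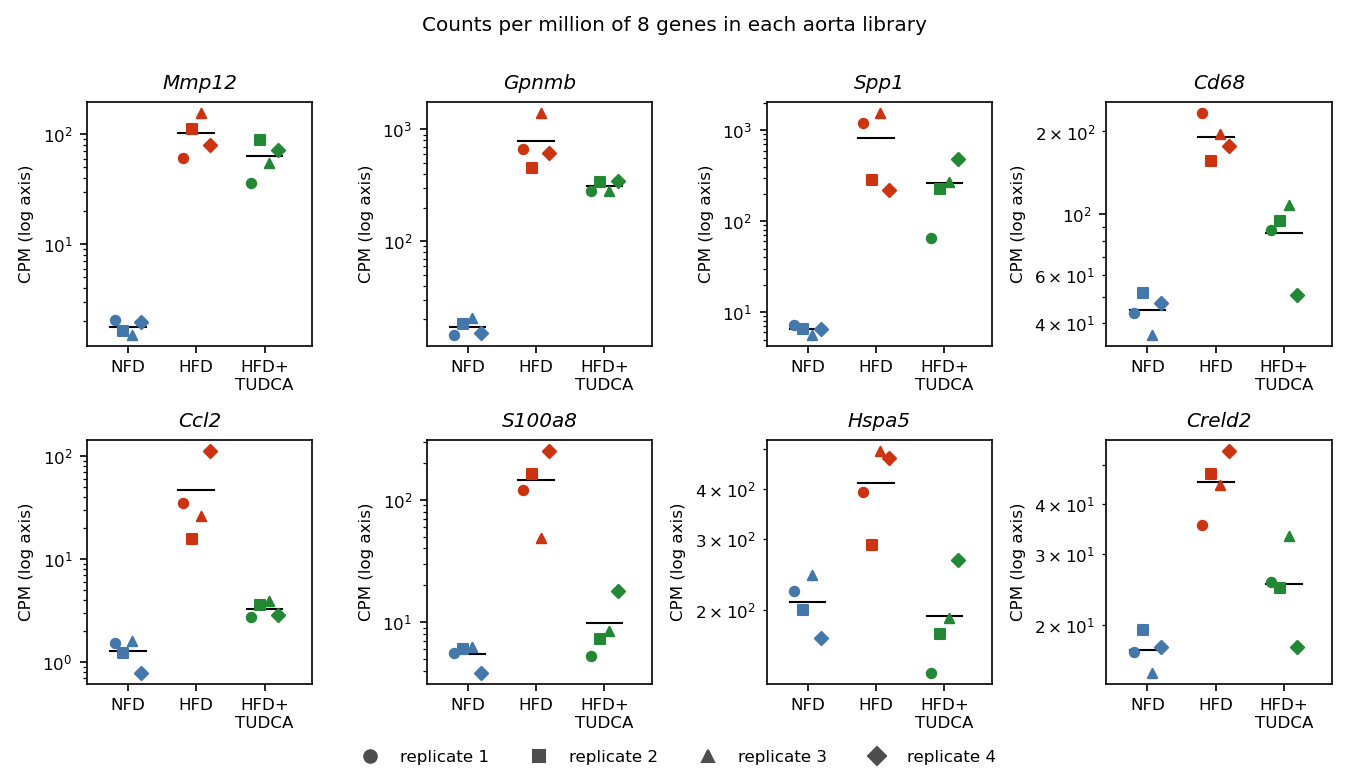
CPM (log axis) of Mmp12, Gpnmb, Spp1, Cd68, Ccl2, S100a8, Hspa5 and Creld2 in each of the 12 aorta libraries. Points are libraries, marker shapes are replicate numbers and black lines are group means (n = 4). Gpnmb averaged 17.2 CPM in NFD, 789 in HFD and 313 in HFD+TUDCA.

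Of 38 gene lists tested with camera, 15 rose and 9 fell, and 3 of these calls held when the correlation between genes was estimated rather than preset: foam cells, matrix proteases, and the unfolded protein response (UPR). The foam cell and lesion macrophage list rose (median log2 fold change 1.62, camera adjusted p = 2.60e-31, and adjusted p = 0.0318 with an estimated correlation). Of its 20 genes 13 rose, 0 fell and 7 did not pass, and 16 rose when adjusted over the list alone. Lgals3 (galectin-3) rose from 67.8 ± 9.43 to 368 ± 109 CPM, the lipid sensor Trem2 from 4.22 ± 1.54 to 53.2 ± 27.3 CPM, and the cholesterol exporters Abcg1 and Abca1 by 3.14-fold and 2.19-fold. The matrix protease and inhibitor list rose as well (median 1.49, adjusted p = 2.22e-25, and adjusted p = 0.0319 with an estimated correlation), with 13 of 18 genes higher and 15 higher when adjusted over the list alone. General macrophage markers rose (median 1.20, adjusted p = 7.93e-17, and adjusted p = 0.0895 with an estimated correlation). Of 20 such markers 13 were higher, and adjusted over the list alone 15 were higher and 2 lower. Cd68 went from 44.8 ± 6.54 to 191 ± 33.3 CPM and cathepsin S (Ctss) from 146 ± 18.2 to 661 ± 247 CPM, while the resident macrophage markers Lyve1 (log2 fold change -0.90 ± 0.25, adjusted p = 0.0706) and Cd163 (-0.31 ± 0.39, adjusted p = 0.709) did not pass.

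Cytokine and chemokine genes rose (median 2.11, camera adjusted p = 8.96e-23, and adjusted p = 0.0895 with an estimated correlation). Among the 27 tested, 15 rose and 0 fell, and 24 rose when adjusted over the list alone. The monocyte chemokine Ccl2 rose from 1.29 ± 0.37 to 47.5 ± 44.3 CPM and Il1b from 1.83 ± 0.56 to 44.6 ± 46.3 CPM. The neutrophil list rose with a median of 3.78 (adjusted p = 8.36e-22, and adjusted p = 0.0873 with an estimated correlation), and 10 of its 13 genes rose by either adjustment, over all genes or adjusted over the list alone. S100a8 and S100a9, the calgranulins of neutrophils, rose 27.0-fold and 24.5-fold, and the receptor Csf3r 4.71-fold. HFD replicate 4 stood apart in this response, with 104 CPM of Csf3 against 2.47 to 7.54 CPM in the other HFD libraries. Blood left in the samples was not tested as a cause of the neutrophil rise. In HFD replicates 1 to 4 the neutrophil score was 4.30, 5.34, 3.32 and 5.62, and the erythroid score 6.42, 7.55, 6.12 and 8.10. In NFD these scores were 1.53 to 2.13 and 5.43 to 6.72. Leukocyte adhesion genes rose (median 0.69, adjusted p = 0.00428, and adjusted p = 0.335 with an estimated correlation), with 2 of 15 genes higher, Vcam1 (2.57-fold) and the integrin gene Itgb2 (2.18-fold), and 4 when adjusted over the list alone. Icam1 did not pass (log2 fold change 2.79 ± 0.99, adjusted p = 0.156), at 1276 CPM in HFD replicate 4 and 65.3 to 95.3 CPM in the other HFD libraries.

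The UPR and ER stress list rose (median 0.48, camera adjusted p = 4.53e-09, and adjusted p = 0.0319 with an estimated correlation). Of its 34 genes 8 rose and 26 did not pass, and 19 rose and 1 fell when adjusted over the list alone. Creld2, an ER protein induced by the UPR, rose from 17.4 ± 1.74 to 45.3 ± 7.75 CPM (log2 fold change 1.39 ± 0.16, edgeR adjusted p = 0.00246). Hspa5 (ENSMUSG00000026864, chromosome 2, 34771970 to 34777547, plus strand) had a log2 fold change of 0.99 ± 0.20 (adjusted p = 0.0231), the disulfide isomerase Pdia4 of 0.84 ± 0.14 (adjusted p = 0.0132) and the secreted ER protein Manf of 0.95 ± 0.18 (adjusted p = 0.0186). The call of Hspa5 was lost without NFD replicate 1, 2, 3 or 4, with an edgeR adjusted p of up to 0.0794 over the fits that left out 1 library, and over all its alternatives the adjusted p ranged from 9.42e-05 to 0.401. The UPR transcription factors Xbp1 (0.78 ± 0.21, adjusted p = 0.0650) and Atf4 (0.79 ± 0.36, adjusted p = 0.248) did not pass, and neither did Ddit3, which encodes CHOP (0.06 ± 0.21, adjusted p = 0.903). Within the HFD group the mean log2 CPM of the list was 6.65 in replicate 4 and 6.40 to 6.41 in the others. B cell and plasma cell genes, which include secretory cells rich in ER, rose beside it (median 0.90, adjusted p = 0.00186, and adjusted p = 0.559 with an estimated correlation). In that list 2 of 13 genes were higher, Ighm and Igkc, and 5 when adjusted over the list alone. Ighm varied from 1825 to 9584 CPM within HFD.

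Genes of cholesterol synthesis fell together (median -0.68, camera adjusted p = 1.94e-09, and adjusted p = 0.164 with an estimated correlation). All 21 had a negative fold change, 3 fell by the test over all genes and 14 when adjusted over the list alone. Cyp51, the lanosterol demethylase, fell 1.99-fold. Adrenal tissue in unequal amounts was not tested as a cause. The list score was 4.91 in NFD replicate 2, with the adrenal gene Cyp11b1 at 0.102 CPM, and 5.28 to 5.42 in the other NFD libraries (16.9 to 849 CPM). It was 4.31 and 4.45 in HFD replicates 1 and 2 (0.184 and 1.06 CPM) and 4.73 and 4.85 in replicates 3 and 4 (146 and 545 CPM). In HFD+TUDCA, with Cyp11b1 at 0 to 0.190 CPM, the score was 4.83 to 5.55. The fatty acid synthesis list fell (median -0.63, adjusted p = 1.07e-04, and adjusted p = 0.351 with an estimated correlation), with 3 of 15 genes lower and 5 when adjusted over the list alone. Those 3 were Acly (5.14-fold), Acaca (3.90-fold) and Me1 (5.61-fold), which supply acetyl-CoA, malonyl-CoA and NADPH. White adipocyte genes fell beside them (median -0.36, adjusted p = 2.25e-04, and adjusted p = 0.335 with an estimated correlation), with 2 of 14 lower and 6 when adjusted over the list alone. One of these was Retn (resistin), which was 2.39-fold lower. The white adipocyte list was fixed as a marker of other tissue that the samples could hold, such as fat around the aorta. Its score was 9.38 to 9.76 in NFD and 8.62 to 9.21 in HFD. Unequal amounts of fat in the samples were not tested as a cause of the falls in adipocyte and fatty acid synthesis genes.

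Heart muscle genes had the largest fall of any list (median -2.09, camera adjusted p = 7.50e-14, and adjusted p = 0.164 with an estimated correlation). Of 13 genes 4 fell, among them Tnnt2 (cardiac troponin T, 3.75-fold), and 12 fell when adjusted over the list alone. Myh6 (ENSMUSG00000040752, chromosome 14, 54941921 to 54966927, minus strand) ranged from 720 to 2036 CPM in NFD and from 106 to 581 CPM in HFD. Within HFD+TUDCA it ranged from 4.05 to 3608 CPM, and heart tissue in unequal amounts was not excluded as a cause of the fall. Mesothelial and epithelial genes fell (median -0.95, adjusted p = 2.82e-04, and adjusted p = 0.402 with an estimated correlation), although 0 of 12 passed over all genes and 2 when adjusted over the list alone. The airway secretory gene Scgb1a1 stood at 529 to 1469 CPM in the NFD libraries and at 0.123, 453, 177 and 3.59 CPM in HFD replicates 1 to 4. Contractile smooth muscle genes fell (median -0.38, adjusted p = 4.14e-05, and adjusted p = 0.346 with an estimated correlation). Of 18 genes 3 were lower and 5 when adjusted over the list alone, including Cnn1 (calponin, 1.83-fold) and Pln (phospholamban, 3.93-fold), which heart muscle also expresses. Cnn1 kept its call in 1 of the 8 fits that left out 1 library (adjusted p up to 0.120) and Pln in 7. Acta2 and Myh11, the main contractile genes, did not pass, with log2 fold changes of -0.42 ± 0.23 (adjusted p = 0.337) and -0.25 ± 0.24 (adjusted p = 0.598). Osteochondrogenic genes fell (median -0.56, adjusted p = 0.00464, and adjusted p = 0.335 with an estimated correlation), with 1 of 15 higher and 4 lower, and 2 and 6 when adjusted over the list alone. Cytl1, a cartilage cytokine, was 2.90-fold lower. The respiratory chain list fell (median -0.22, adjusted p = 0.0279, and adjusted p = 0.708 with an estimated correlation) with 0 of 18 genes past the test by either adjustment, over all genes or adjusted over the list alone. Adventitial fibroblast genes fell (median -0.48, adjusted p = 0.0407, and adjusted p = 0.559 with an estimated correlation), with 1 of 13 higher and 1 lower, Cd34 (2.07-fold), and 2 and 7 when adjusted over the list alone.

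The remaining lists that rose covered interferon response genes (median 1.25, camera adjusted p = 3.07e-08, and adjusted p = 0.351 with an estimated correlation), with 2 of 19 higher and 14 when adjusted over the list alone. The interferon score was 6.49 in HFD replicate 4 against 4.44 to 4.95 in the other HFD libraries, and without that library the median was 0.67. Immediate early and heat shock genes rose (median 1.35, adjusted p = 2.49e-06, and adjusted p = 0.351 with an estimated correlation), with 2 of 15 higher and 12 when adjusted over the list alone. This list was fixed as a sign of handling and tissue collection, its score was 7.63 in HFD replicate 4 against 5.26 to 5.72 in the other HFD libraries, and without that library the median was 0.80. Coagulation and fibrinolysis genes rose (median 0.65, adjusted p = 1.06e-05, and adjusted p = 0.164 with an estimated correlation), with 5 of 15 higher and 1 lower, and 7 and 1 when adjusted over the list alone. Among them F10, coagulation factor X, was 11.5-fold higher at 15.8 ± 4.85 against 1.37 ± 0.42 CPM. The oxidative stress list rose (median 0.54, adjusted p = 4.86e-04, and adjusted p = 0.163 with an estimated correlation), with 4 of 19 genes higher and 5 when adjusted over the list alone. These held Cybb (3.11-fold) and Ncf4 (3.49-fold), subunits of the phagocyte NADPH oxidase. Antigen presentation rose (median 0.71, adjusted p = 1.48e-05, and adjusted p = 0.417 with an estimated correlation), with 2 of 14 higher and 9 when adjusted over the list alone. For the cell cycle the median was 0.95 (adjusted p = 2.84e-05, and adjusted p = 0.417 with an estimated correlation), with 1 of 16 higher and 7 when adjusted over the list alone. For mast cells it was 0.46 (adjusted p = 0.0323, and adjusted p = 0.351 with an estimated correlation), with 1 of 7 higher by either adjustment, over all genes or adjusted over the list alone.

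Over the 14 alternatives of HFD vs NFD many of these lists moved. The calls least often kept were those of mast cells (5 of 14, medians from 0.32 to 0.64), adventitial fibroblasts (6, -0.61 to -0.18), the respiratory chain (6, -0.51 to -0.05), osteochondrogenic genes (8, -0.70 to -0.05) and B cells and plasma cells (10, 0.42 to 1.22). In 11 of 14 the calls were kept for the interferon response (0.672 to 1.505), leukocyte adhesion (0.25 to 0.84), antigen presentation (0.46 to 0.85), the cell cycle (0.69 to 1.13), immediate early and heat shock (0.80 to 1.62), fatty acid synthesis (-0.90 to -0.36), mesothelial and epithelial (-1.48 to -0.68) and contractile smooth muscle genes (-0.50 to -0.26). In 12 of 14 they were kept for white adipocyte (-0.60 to -0.30), oxidative stress (0.23 to 0.64), coagulation (0.44 to 0.83) and heart muscle genes (-2.76 to -1.77).

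Another 14 lists did not pass, with camera adjusted p from 0.0668 to 0.943. Their medians were 0.98 for erythroid, 0.34 for bile acid receptor and transport, 0.33 for platelet, 0.19 for fatty acid oxidation, 0.19 for extracellular matrix, 0.19 for mitochondrially encoded and 0.10 for Y-linked genes. They were -0.58 for thymocyte, -0.40 for skeletal muscle, -0.15 for endothelial, -0.11 for T cell and NK cell, -0.11 for brown adipocyte, -0.10 for Schwann cell and neuron, and -0.00 for circadian clock genes. Of their members 1 bile acid transporter was higher and 1 clock gene lower over all genes. When adjusted over the list alone there were 2 higher in the bile acid list, 3 higher in the matrix list, and 2 lower in the Schwann cell and 3 lower in the clock list. The test of the Y-linked list pointed down against a positive median, and the means of the bile acid (-0.12), T cell and NK cell (0.01) and brown adipocyte lists (0.04) differed in sign from their medians. In pathways of the deposited annotation, genes that rose were over-represented in 54 of 332 (Fisher's exact test, one-sided, adjusted over pathways) and genes that fell in 0, where camera on the same pathways called 83 higher and 17 lower. These 54 included osteoclast differentiation (30 of 118 genes), lysosome (31 of 128), phagosome (40 of 220) and NF-kappa B signalling (34 of 176).

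**Figure D2:**
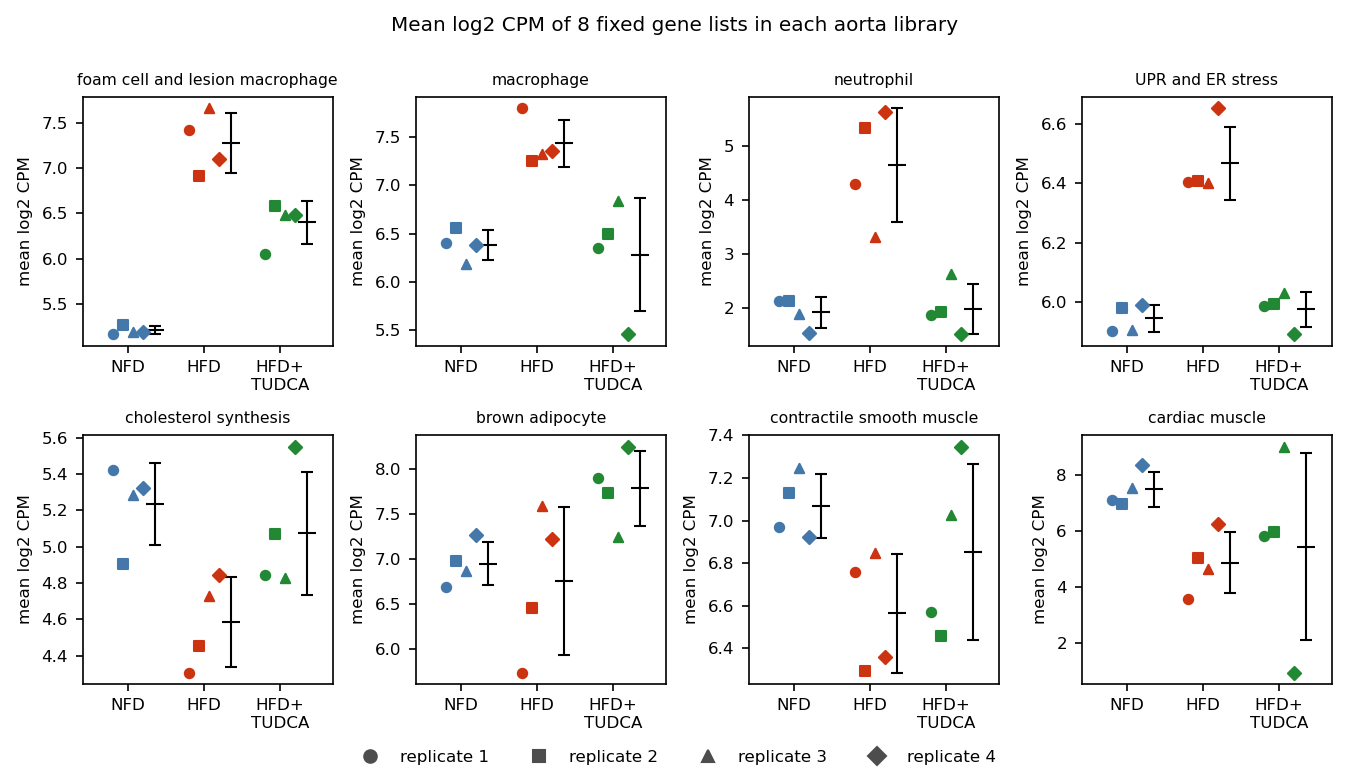
Mean log2 CPM of 8 gene lists in each library, with the group mean ± SD (n = 4) as a black bar beside the points and marker shapes for replicate numbers. The UPR list averaged 5.94 in NFD, 6.47 in HFD and 5.97 in HFD+TUDCA, and the cardiac muscle list spread most within HFD+TUDCA (SD 3.35).

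The comparison of HFD+TUDCA with HFD asked what TUDCA changed on the high-fat diet. Genes of cytokines, neutrophils, macrophages and the UPR were lower as groups with TUDCA, and genes of brown fat, fatty acid oxidation and the respiratory chain were higher as groups, while no single gene passed the test of edgeR. With an estimated correlation between genes only the UPR list kept its call (adjusted p = 0.0148), and the other 6 lost it (0.0757 to 0.396). S100a8 stood at 9.72 ± 5.63 CPM with TUDCA against 146 ± 85.1 CPM without (log2 fold change -3.85 ± 0.57, edgeR adjusted p = 0.147). Ccl2 stood at 3.29 ± 0.56 against 47.5 ± 44.3 CPM (-3.81 ± 0.59, adjusted p = 0.148) and Cd68 at 85.1 ± 24.6 against 191 ± 33.3 CPM (-1.15 ± 0.24, adjusted p = 0.185). Hspa5 stood at 193 ± 53.0 against 414 ± 93.4 CPM (-1.07 ± 0.26, adjusted p = 0.237). In each of these 4 genes every HFD+TUDCA library lay below every HFD library.

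Of 14587 genes tested, edgeR called 0, with the lowest adjusted p at 0.147. At an unadjusted p under 0.05 there were 1745 genes, 791 higher and 954 lower with TUDCA. DESeq2 called 352 (78 higher and 274 lower), limma-voom 0, limma-trend on FPKM 0, and edgeR with all 12 libraries in 1 fit 115 (9 higher and 106 lower). In simulated data of this comparison, edgeR recovered 60.9% of genes changed 4-fold, 2.99% of those changed 2-fold and 0 of those changed 1.5-fold. Libraries of the 2 groups did not overlap in 7.44% of the genes, where the average over all splits of the 8 libraries is 2.86%. Genes are correlated, so a single split can lie far from that average, and the share was not set against other splits. By unadjusted p, 7 of 35 splits, the real one included, gave at least 1745 genes.

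The genes with the lowest unadjusted p on the lower side were Ifi205 (log2 fold change -2.38 ± 0.28), Alox5ap (-1.47 ± 0.21), Ccl9 (-1.95 ± 0.28), Slfn4 (-2.97 ± 0.43) and Padi4 (-1.97 ± 0.29), each with an edgeR adjusted p of 0.147. Alox5ap is needed for leukotriene synthesis, Ccl9 is a chemokine and Padi4 citrullinates histones in neutrophils. On the higher side they were Nnat (2.00 ± 0.34, adjusted p = 0.148), Mmab (0.95 ± 0.19), Axin2 (1.02 ± 0.21), Pgm1 (0.88 ± 0.18) and Inka2 (0.91 ± 0.19, adjusted p = 0.186). The foam cell genes Gpnmb (-1.32 ± 0.35, adjusted p = 0.268), Spp1 (-1.63 ± 0.76, adjusted p = 0.436) and Mmp12 (-0.67 ± 0.35, adjusted p = 0.483) did not pass either, at 313 ± 35.2, 261 ± 170 and 63.0 ± 22.7 CPM with TUDCA.

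By camera, 17 of the 38 lists fell and 10 rose with TUDCA, and the UPR list alone kept its call with an estimated correlation. In the counts over all genes, 0 members of any list passed. Cytokine and chemokine genes fell (median -2.01, camera adjusted p = 2.34e-25, and adjusted p = 0.0757 with an estimated correlation), and 19 of 27 fell when adjusted over the list alone. Neutrophil genes fell (median -3.24, adjusted p = 5.90e-23, and adjusted p = 0.0757 with an estimated correlation), with 10 of 13 lower when adjusted over the list alone. Csf3r stood at 20.3 ± 4.55 against 56.7 ± 14.2 CPM. Blood left in the samples was not tested as a cause of the neutrophil fall. General macrophage markers fell (median -1.13, adjusted p = 1.17e-20, and adjusted p = 0.104 with an estimated correlation), with 15 of 20 lower when adjusted over the list alone. The foam cell and lesion macrophage list fell (median -0.85, adjusted p = 7.36e-12, and adjusted p = 0.0757 with an estimated correlation), with 10 of 20 lower when adjusted over the list alone. Abcg1 (log2 fold change -1.40 ± 0.22) and Abca1 (-1.22 ± 0.22), the cholesterol exporters, had the smallest unadjusted p in it, and Trem2 had -1.52 ± 0.38 (adjusted p = 0.246). Matrix protease and inhibitor genes fell (median -0.86, adjusted p = 9.43e-13, and adjusted p = 0.0757 with an estimated correlation), with 10 of 18 lower when adjusted over the list alone.

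The UPR and ER stress list fell (median -0.45, camera adjusted p = 3.90e-09, and adjusted p = 0.0148 with an estimated correlation). Of its 34 genes 29 had a negative fold change, and 7 fell when adjusted over the list alone. Manf (log2 fold change -0.93 ± 0.19, edgeR adjusted p = 0.169), Pdia6 (-0.61 ± 0.15, adjusted p = 0.237) and Creld2 (-0.81 ± 0.21, adjusted p = 0.257) were among the members with the smallest unadjusted p, and Ddit3 had -0.19 ± 0.25 (adjusted p = 0.790). The mean log2 CPM of the list was 5.97 ± 0.06 with TUDCA, 6.47 ± 0.12 in HFD and 5.94 ± 0.05 in NFD. B cell and plasma cell genes did not pass here (median -0.01, camera adjusted p = 0.577). Their mean log2 CPM was 4.45 in HFD+TUDCA replicate 4 and 7.35 to 7.76 in the other HFD+TUDCA libraries.

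Further lists that fell were the interferon response (median -1.27, camera adjusted p = 1.24e-12, and adjusted p = 0.273 with an estimated correlation), with 13 of 19 lower when adjusted over the list alone, among them Ifi44 at 2.03 ± 0.42 against 6.87 ± 1.81 CPM. HFD replicate 4 had the highest score of this list (6.49, others in HFD 4.44 to 4.95), and over the 15 alternatives the median ranged from -1.51 to -0.58, the weakest with both HFD replicate 4 and HFD+TUDCA replicate 4 left out. Coagulation and fibrinolysis fell (median -0.64, adjusted p = 2.47e-08, and adjusted p = 0.0757 with an estimated correlation), with 6 of 15 lower when adjusted over the list alone, among them F10 (log2 fold change -1.84 ± 0.27). Leukocyte adhesion fell (median -0.57, adjusted p = 0.00102, and adjusted p = 0.170 with an estimated correlation), with 3 of 15 lower when adjusted over the list alone. The median ranged from -0.80 to -0.25 over the alternatives, 11 of 15 passed, and the score was 7.03 in HFD replicate 4 against 5.46 to 6.04 in the other HFD libraries. Sele (E-selectin) stood at 0.903 to 2.13 CPM with TUDCA and at 15.6, 3.79, 3.41 and 128 CPM in HFD replicates 1 to 4, so that its HFD mean rests mainly on replicate 4. Vcam1 stood at 126 ± 45.8 against 292 ± 114 CPM. Oxidative stress genes fell (median -0.28, adjusted p = 0.0198, and adjusted p = 0.170 with an estimated correlation), with 2 of 19 lower when adjusted over the list alone, and Hmox1 (heme oxygenase 1) stood at 36.9 ± 7.93 against 135 ± 85.0 CPM. The bile acid receptor and transport list fell (median -0.56, adjusted p = 0.0202, and adjusted p = 0.170 with an estimated correlation), with 2 of 5 lower when adjusted over the list alone. That call was kept in 7 of 15 alternatives (medians from -0.93 to -0.01) and was lost without HFD replicate 4 and without HFD+TUDCA replicate 4, where the score was 1.09 against 1.88 to 2.34 in the other HFD+TUDCA libraries. Its member Nr1h4, the nuclear bile acid receptor FXR, stood at 0.213 ± 0.187 with TUDCA against 0.805 ± 0.198 CPM and did not pass (log2 fold change -1.86 ± 0.65, adjusted p = 0.346). The extracellular matrix list fell (median -0.54, adjusted p = 0.0202, and adjusted p = 0.634 with an estimated correlation) with 0 of 22 lower when adjusted over the list alone, and Col1a1, a fibrillar collagen, had a log2 fold change of -0.82 ± 0.41 (adjusted p = 0.462).

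The last lists that fell were immediate early and heat shock genes (median -0.81, camera adjusted p = 0.00111, and adjusted p = 0.555 with an estimated correlation), the cell cycle (median -0.60, adjusted p = 0.00140, and adjusted p = 0.555 with an estimated correlation), erythroid genes (median -0.88, adjusted p = 0.00728, and adjusted p = 0.533 with an estimated correlation), antigen presentation (median -0.34, adjusted p = 0.00913, and adjusted p = 0.609 with an estimated correlation) and mast cell genes (median -0.15, adjusted p = 0.0202, and adjusted p = 0.555 with an estimated correlation). In these 5 lists, 0, 0, 1, 1 and 1 genes fell when adjusted over the list alone. The immediate early and heat shock list was fixed as a sign of handling. Its score was 7.63 in HFD replicate 4, 5.26 to 5.72 in the other HFD libraries and 5.197 to 5.429 in HFD+TUDCA. Without HFD replicate 4 it did not pass (median -0.07, adjusted p = 0.126, within 2.15e-07 to 0.555 over its alternatives). The falls of antigen presentation, cell cycle and mast cell genes depended on HFD+TUDCA replicate 4. Antigen presentation genes averaged 6.17 log2 CPM in it, 8.07 to 8.27 in the others of that group and 7.42 to 8.78 in HFD, and without it the list had a median of -0.02 and did not pass (medians from -0.54 to 0.17 over the alternatives, 8 of 15 past). The cell cycle score was 1.19 in that library against 2.702 to 3.255 in the others of its group, and without it the median was -0.31 and did not pass (-0.88 to -0.23, 9 of 15 past). The mast cell score was 2.30 against 3.50 to 4.38, and without the library the median was 0.11 and did not pass (-0.65 to 0.11, 9 of 15 past).

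Genes of fat cells and of energy metabolism rose as groups with TUDCA. The brown and white adipocyte lists were fixed as markers of other tissue that the samples could hold, such as fat around the aorta. Ucp1 ranged from 308 to 1754 CPM within HFD and from 2031 to 4931 CPM within HFD+TUDCA. Unequal amounts of fat in the samples were not tested as a cause of these rises. The brown adipocyte list rose (median 0.73, camera adjusted p = 1.20e-07, and adjusted p = 0.273 with an estimated correlation), with 11 of 12 genes at a positive fold change and 0 past the test when adjusted over the list alone. Ucp1, the uncoupling protein of brown fat, stood at 3555 ± 1191 against 1067 ± 783 CPM (log2 fold change 1.78 ± 0.58, edgeR adjusted p = 0.322), and Elovl3 at 187 ± 87.6 against 38.2 ± 30.6 CPM. Fatty acid oxidation rose (median 0.69, adjusted p = 1.98e-07, and adjusted p = 0.319 with an estimated correlation), as did the respiratory chain (median 0.53, adjusted p = 2.47e-08, and adjusted p = 0.396 with an estimated correlation), with 0 genes of either past the test when adjusted over the list alone. Mitochondrially encoded genes, a list fixed as a measure of RNA quality, also passed (median 0.40, adjusted p = 0.0124, and adjusted p = 0.609 with an estimated correlation), with 0 genes when adjusted over the list alone. Their score was 12.97 in HFD+TUDCA replicate 4 against 11.43 to 12.28 in the others of that group, and over the alternatives the median ranged from -0.07 to 0.68 and the adjusted p from 5.95e-05 to 0.886. Cholesterol synthesis rose (median 0.54, adjusted p = 5.45e-07, and adjusted p = 0.299 with an estimated correlation), with 3 of 21 higher when adjusted over the list alone. Nsdhl (log2 fold change 1.07 ± 0.25) and Insig1 (1.72 ± 0.46) had positive fold changes. White adipocyte genes rose (median 0.43, adjusted p = 8.68e-04, and adjusted p = 0.396 with an estimated correlation), with 1 of 14 higher when adjusted over the list alone, and Plin1, a coat protein of lipid droplets, stood at 948 ± 256 against 454 ± 110 CPM. Fatty acid synthesis rose (median 0.58, adjusted p = 0.0284, and adjusted p = 0.601 with an estimated correlation), with Fasn at 6700 ± 3176 against 1979 ± 1300 CPM and 0 of 15 genes past the test when adjusted over the list alone.

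Muscle and cartilage genes rose as well, namely contractile smooth muscle (median 0.41, camera adjusted p = 0.00424, and adjusted p = 0.555 with an estimated correlation), skeletal muscle (median 0.87, adjusted p = 0.00260, and adjusted p = 0.555 with an estimated correlation) and osteochondrogenic genes (median 0.75, adjusted p = 0.0216, and adjusted p = 0.555 with an estimated correlation), each with 0 genes past the test when adjusted over the list alone. The skeletal muscle score ranged from 0.863 in replicate 4 to 6.02 within HFD+TUDCA and from 1.12 to 5.35 within HFD, and over the alternatives the median ranged from 0.58 to 2.45 and 11 of 15 passed. Acta2 (log2 fold change 0.42 ± 0.30, adjusted p = 0.592) and Myh11 (0.33 ± 0.37, adjusted p = 0.747) did not pass. Heart muscle genes did not pass as a list (median 1.38, adjusted p = 0.0613), and within HFD+TUDCA Myh6 ranged from 4.05 CPM in replicate 4 to 3608 CPM in replicate 3. Another 9 lists did not pass, with medians of 0.61 for mesothelial and epithelial, 0.39 for thymocyte, 0.30 for Schwann cell and neuron, 0.00 for circadian clock, -0.07 for endothelial, -0.25 for platelet, -0.26 for adventitial fibroblast, -0.28 for T cell and NK cell and -0.43 for Y-linked genes. Their camera adjusted p ranged from 0.0697 to 0.863, with 1 T cell and NK cell gene lower when adjusted over the list alone, and the Schwann cell and neuron list had a mean of -0.06.

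Other lists called in HFD+TUDCA vs HFD moved over the 15 alternatives too. The call was kept in 7 for fatty acid synthesis (medians from 0.36 to 0.85), in 8 for extracellular matrix (-0.76 to -0.29), osteochondrogenic (0.45 to 0.93) and mitochondrially encoded genes, in 9 for erythroid (-1.17 to -0.20) and oxidative stress genes (-0.38 to -0.21), and in 10 for contractile smooth muscle genes (0.01 to 0.55) and the immediate early and heat shock list (-1.08 to -0.07). It was kept in 11 for white adipocyte genes (0.25 to 0.60), in 12 for brown adipocyte (0.58 to 1.17), fatty acid oxidation (0.33 to 1.01), respiratory chain (0.35 to 0.81) and cholesterol synthesis genes (0.40 to 0.67), in 13 for cytokine and chemokine (-2.37 to -1.48), coagulation (-0.80 to -0.50) and matrix protease genes (-1.14 to -0.69), and in 14 for the UPR (-0.49 to -0.27).

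**Figure D3:**
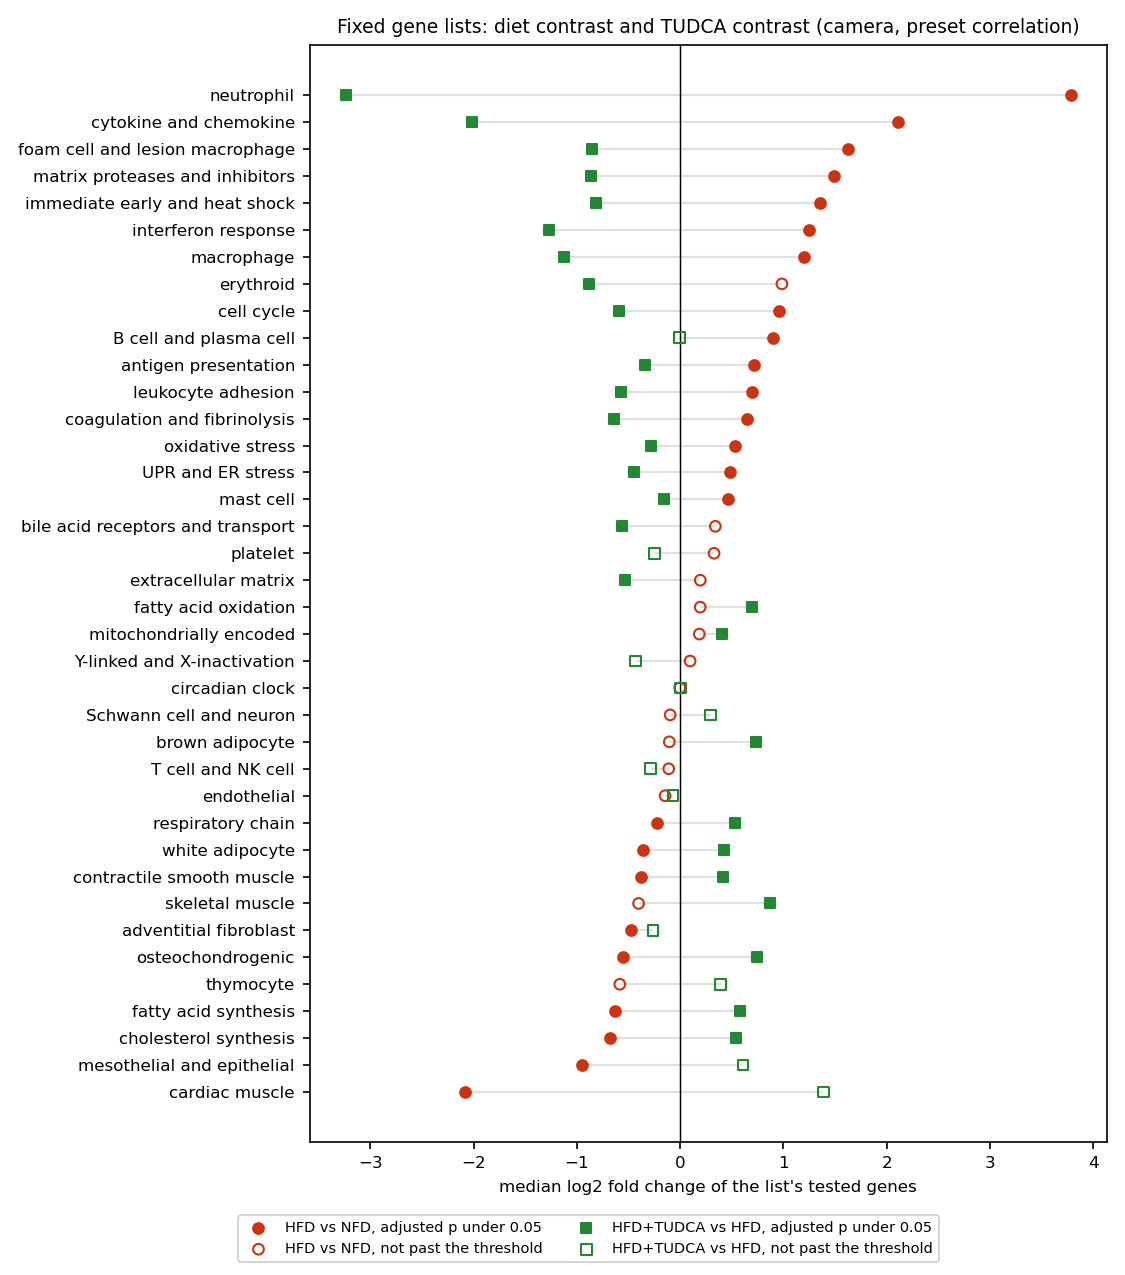
Median log2 fold change of the tested genes of each of 38 lists in HFD vs NFD (circles) and in HFD+TUDCA vs HFD (squares), joined by a grey line. Filled symbols passed camera at an adjusted p under 0.05 with the preset correlation. The neutrophil list lay at 3.78 in the diet comparison and at -3.24 in the TUDCA comparison.

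The comparison of HFD+TUDCA with NFD asked what differed from the normal diet in mice that received both the high-fat diet and TUDCA. Foam cell genes were higher than on the normal diet, and the UPR list did not pass the test. Gpnmb (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929, plus strand) was 18.1-fold higher at 313 ± 35.2 against 17.2 ± 2.88 CPM, and Mmp12 (ENSMUSG00000049723, chromosome 9, 7344381 to 7369499, plus strand) was 35.2-fold higher at 63.0 ± 22.7 against 1.79 ± 0.26 CPM. Sult1a1, a sulfotransferase, was 2.83-fold lower at 62.0 ± 5.47 against 175 ± 11.7 CPM. Hspa5 did not pass, with a log2 fold change of -0.12 ± 0.20 (edgeR adjusted p = 0.890), and neither did Ccl2 (1.35 ± 0.32, adjusted p = 0.146) or Abca1 (-0.13 ± 0.16, adjusted p = 0.848).

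Of 14942 genes tested with edgeR, 29 changed, 15 higher and 14 lower in HFD+TUDCA, and 26 of them at least 2-fold. At an unadjusted p under 0.05 there were 1711 genes, and the libraries did not overlap in 7.36% of the genes. The average over all splits of the 8 libraries is 2.86%, from which a single split can lie far, because genes are correlated. DESeq2 called 533 genes, limma-trend on log2(FPKM + 1) called 50, and edgeR with the replicate number as a block called 8 (5 higher and 3 lower). The count was 7 without NFD replicate 1, 4 without NFD replicate 2, 9 without NFD replicate 3, 19 without HFD+TUDCA replicate 1, 11 without HFD+TUDCA replicate 2, 140 without HFD+TUDCA replicate 3 and 682 without HFD+TUDCA replicate 4. Added after the data were seen, the heart muscle score as a covariate gave 137 genes and the mesothelial and epithelial score gave 64. Of 21 named genes called here, Gpnmb, Mmp12 and Sult1a1 kept their call in all 8 fits that left out 1 library, while Rdh16, Fbp2, Lyve1 and Mfap5 kept it in 2 and Atp6v0d2, Trem2, Lilrb4b, Mup11 and F13a1 in 3.

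Among the 15 genes that rose, Gpnmb had a log2 fold change of 4.18 ± 0.17 (edgeR adjusted p = 1.57e-05), Mmp12 of 5.14 ± 0.31 (adjusted p = 3.36e-04) and Spp1 of 5.32 ± 0.56 (adjusted p = 0.00971). Trem2 rose 4.36-fold, the proton pump subunit gene Atp6v0d2 10.3-fold and Il1rn, the interleukin-1 receptor antagonist, 3.97-fold. Elovl3, a fatty acid elongase of brown fat, rose 20.6-fold, and Rdh16, Fbp2 and Lilrb4b rose 15.5-fold, 6.85-fold and 6.31-fold, the last with uncertain counts because of its near copy Lilrb4a. Serpina3b fell 47.3-fold to 0.917 ± 0.690 CPM. Cyp1a1, a target of the aryl hydrocarbon receptor, fell 4.64-fold, and Fkbp5, a target of the glucocorticoid receptor, fell 2.90-fold. In HFD vs NFD, Cyp1a1 fell as well (log2 fold change -1.83 ± 0.43, adjusted p = 0.0466), and Fkbp5 did not pass (0.07 ± 0.35, adjusted p = 0.937). Lyve1 fell 3.32-fold and Cd163 2.41-fold, both markers of resident macrophages. Cd34 and Mfap5, of adventitial fibroblasts, fell 2.63-fold and 2.21-fold, and F13a1, the A chain of coagulation factor XIII, fell 2.09-fold. Mup11 and Cldn22 fell too, with the uncertain counts described for the Mup family and for Cldn22 (at least 133-fold lower over the group).

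By camera 10 lists rose and 8 fell, and the foam cell and lesion macrophage list alone kept its call with an estimated correlation (median 0.48, camera adjusted p = 4.14e-28, and adjusted p = 0.00760 with an estimated correlation). Of its 20 genes 5 rose, and 10 rose and 1 fell when adjusted over the list alone. Matrix protease genes rose (median 0.40, adjusted p = 3.54e-10, and adjusted p = 0.118 with an estimated correlation), with 1 of 18 higher, Mmp12, and 3 when adjusted over the list alone. Fatty acid oxidation rose (median 0.80, adjusted p = 6.77e-15, and adjusted p = 0.288 with an estimated correlation), with 0 of 17 past the test over all genes and 13 when adjusted over the list alone. Acot2 (log2 fold change 1.86 ± 0.36) and Acads (0.84 ± 0.21), enzymes of mitochondrial fatty acid metabolism, were members with small unadjusted p. Brown adipocyte genes rose (median 0.62, adjusted p = 3.65e-10, and adjusted p = 0.292 with an estimated correlation), with 1 of 12 higher, Elovl3, and 6 when adjusted over the list alone. Adventitial fibroblast genes fell (median -0.37, adjusted p = 4.95e-07, and adjusted p = 0.288 with an estimated correlation), with 2 of 13 lower and, when adjusted over the list alone, 1 higher and 5 lower. Cytokine and chemokine genes rose (median 0.39, adjusted p = 6.99e-05, and adjusted p = 0.648 with an estimated correlation), with 0 of 25 past the test over all genes and, when adjusted over the list alone, 5 higher and 1 lower. B cell and plasma cell genes rose (median 1.03, adjusted p = 4.47e-04, and adjusted p = 0.786 with an estimated correlation), with 0 of 13 past the test and 1 when adjusted over the list alone.

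For the UPR list the median was -0.03 (camera adjusted p = 0.480) and for the macrophage list 0.09 (adjusted p = 0.388), with 2 of its 20 genes lower, Lyve1 and Cd163, and 1 higher and 3 lower when adjusted over the list alone. The UPR list had a mean of 0.05 and its test pointed up, and the macrophage list a mean of -0.01 with a test that pointed down. A further 11 lists passed camera and were lost with an estimated correlation, at adjusted p from 0.288 to 0.803. The lists that rose in this way were immediate early and heat shock (median 0.51), respiratory chain (0.29), mitochondrially encoded (0.41) and neutrophil genes (0.57). Those that fell were fatty acid synthesis (-0.35), T cell and NK cell (-0.36), mesothelial and epithelial (-0.54), cardiac muscle (-0.69), extracellular matrix (-0.25), endothelial (-0.18) and Y-linked genes (-0.47). Over all genes 0 of their members passed. When adjusted over the list alone 5 immediate early and heat shock, 1 respiratory chain and 2 neutrophil genes were higher. By the same adjustment 2 fatty acid synthesis, 1 endothelial and 1 Y-linked gene were lower, and 2 matrix genes were higher and 8 lower. In some of these 11 lists HFD+TUDCA replicate 4 stood apart from the others of its group. Its score was 1.24 for T cell and NK cell (others 3.41 to 3.94), 0.927 for cardiac muscle (5.82 to 9.04) and 12.97 for mitochondrially encoded genes (11.43 to 12.28). No pathway of the deposited annotation was over-represented among the genes that rose or fell (0 of 332 in either direction, Fisher's exact test), where camera on the same pathways called 44 higher and 7 lower.

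The alternatives of HFD+TUDCA vs NFD numbered 14 per list. The foam cell call was kept in 13 of them with medians from 0.32 to 1.19, that of matrix proteases in 12 (0.34 to 0.75) and that of B cells and plasma cells in 11 (0.61 to 1.37). It was kept in 10 for mitochondrially encoded (0.10 to 0.64), fatty acid synthesis (-0.56 to -0.27), T cell and NK cell (-0.73 to -0.04) and mesothelial and epithelial genes (-1.42 to -0.23), and in 9 for cardiac muscle genes (-2.06 to -0.29). For extracellular matrix (-0.45 to -0.13), endothelial (-0.23 to -0.11), neutrophil (0.06 to 0.69) and Y-linked genes (-0.72 to -0.35) it was kept in 6, 5, 5 and 4.

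Fold changes of the diet comparison and of the TUDCA comparison ran opposite to each other across 14509 genes (Pearson r = -0.720, Spearman rho = -0.685, across genes, which are not independent replicates). Both comparisons use the same HFD libraries with opposite sign, so unchanged groups already give a negative value, which was -0.503 on average over 50 simulations (lowest -0.528, highest -0.460). The simulations drew each gene independently, without the correlation between genes of real libraries. Their range is therefore too narrow to judge r, the covariance or the gene counts given here. Of 100 splits of the real 12 libraries, the real one included, 11 gave r as low as -0.720, and the lowest other was -0.823. The covariance was -0.300 against a simulated -0.0855. With the HFD libraries split 2 and 2 so that the comparisons shared none, r ranged from -0.400 to -0.254 and the covariance from -0.280 to -0.183. At an unadjusted p under 0.05 in both, 978 genes went opposite ways and 13 the same way. Simulation gave 130 and 1.16, and independent lists would give 117 genes up then down, 66.8 down then up and 178 the same way. By adjusted p, 0 genes passed in both comparisons, since edgeR called 0 in the TUDCA comparison, with 1745 there at an unadjusted p under 0.05 and 352 by DESeq2.

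**Figure D4:**
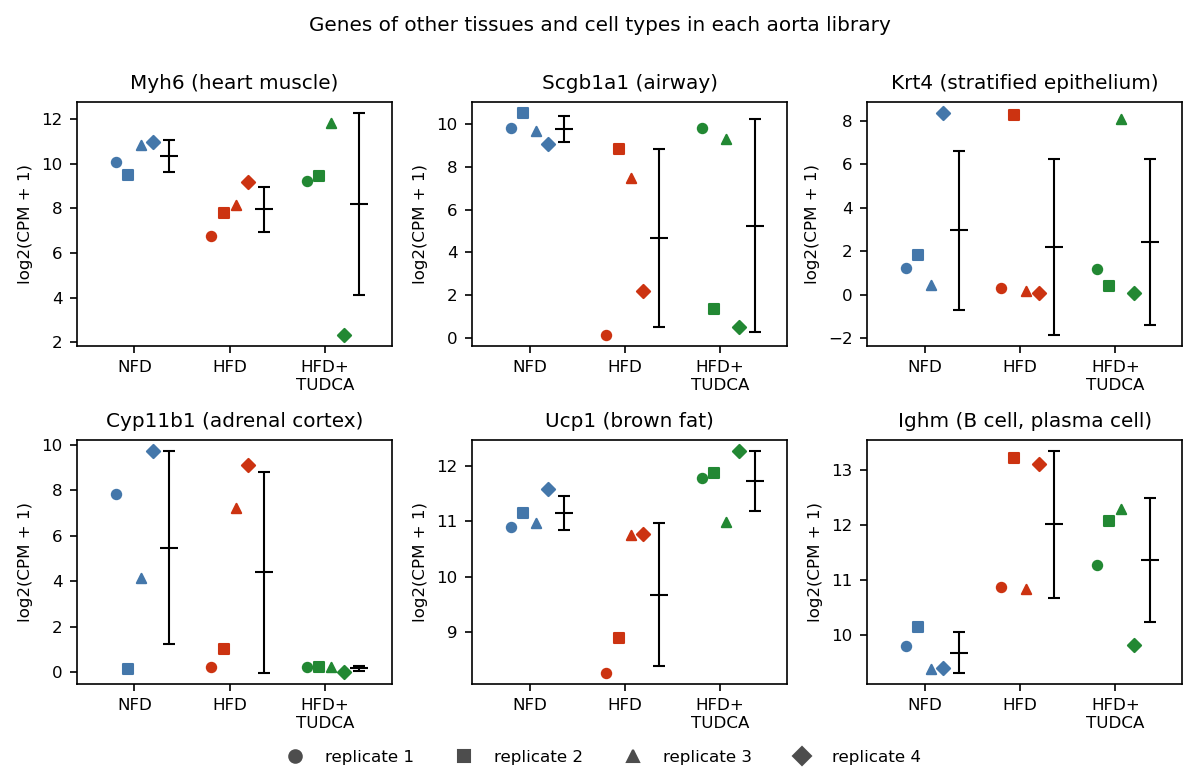
Levels as log2(CPM + 1) of Myh6 (heart muscle), Scgb1a1 (airway), Krt4 (stratified epithelium), Cyp11b1 (adrenal cortex), Ucp1 (brown fat) and Ighm (B cells and plasma cells) in each library, with the group mean ± SD (n = 4) beside the points. Levels differ widely within groups, as for Myh6 at 4.05 and 3608 CPM in 2 of the HFD+TUDCA libraries.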

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

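The tests of other splits for the opposition of fold changes, of the artery wall share, of the common factor of heart genes, of plasma cells and of the trends taken off the UPR score were chosen after the result each bears on had been seen. In groups of 4 libraries, a library far from the other 3 was looked for in 114 list scores, where 5 were found and chance gives 5.70, and in 285 gene levels, where 18 were found and chance gives 14.25. The UPR score was 6.65 in HFD replicate 4 (others 6.40 to 6.41), the endothelial score 6.36 in NFD replicate 1 (6.54 to 6.58), and the matrix protease score 6.31 in HFD replicate 2 (6.87 to 6.96). In HFD+TUDCA replicate 4 the B cell and plasma cell score was 4.45 (7.35 to 7.76) and the antigen presentation score 6.17 (8.07 to 8.27).

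In HFD, Icam1 stood at 1276 CPM in replicate 4 (others 65.3 to 95.3), Atf4 at 449 CPM in replicate 4 (145 to 170), Abca1 at 419 CPM in replicate 1 (248 to 254), Mmab at 16.8 CPM in replicate 1 (24.3 to 25.6) and Cnn1 at 227 CPM in replicate 3 (140 to 145). In NFD, Apoa1 stood at 5.02 CPM and Mfap5 at 64.5 CPM in replicate 1, Il6 at 0.153 CPM in replicate 2 (0 in the others), Csf3 at 0.151 CPM in replicate 3 (0 in the others), and Cybb at 23.3 and F13a1 at 103 CPM in replicate 4. In HFD+TUDCA replicate 4, Csf3 was at 0, Hmox1 at 25.2, Icam1 at 38.1 and Igkc at 345 CPM (2053 to 2405 in the other libraries of the group). Ptx3 stood at 1.87 CPM in HFD+TUDCA replicate 3, and Ifi205 at 3.61 and Slfn4 at 0.531 CPM in replicate 1.

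Of the 35 ways to split the 8 libraries of HFD and NFD into 4 and 4, only 1, the real one, gave 720 changed genes. The highest other gave 1. This argues against chance but does not exclude it, since 1 of 35 is the smallest share that 35 splits can give. The same holds for the 29 genes of HFD+TUDCA vs NFD (1 of 35, highest other 1). At an unadjusted p under 0.05, however, 4 of 35 splits, the real one included, gave at least the real 1711 genes there. For the 0 genes of HFD+TUDCA vs HFD by edgeR (352 by DESeq2), every one of the 35 splits must give as many, so their count decides nothing (highest other 38). At an unadjusted p under 0.05 the real split gave 1745 genes, and 7 of 35 splits gave as many (highest other 3429), so chance cannot be excluded. For numbers of lists chance cannot be excluded either, with 7 of 35 splits giving at least 24 in HFD vs NFD (highest other 29), 4 of 35 giving at least 27 in HFD+TUDCA vs HFD (27) and 13 of 35 giving at least 18 in HFD+TUDCA vs NFD (23). For the opposition, 11 of 100 splits of the 12 libraries gave a correlation as low as -0.720, the lowest other being -0.823, so chance cannot be excluded. In HFD+TUDCA vs NFD another split reached 4125 genes at an unadjusted p under 0.05 against the real 1711, which like the 3429 above points to a structure of the samples other than the groups.

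Macrophage, cytokine and neutrophil genes were lower as lists with TUDCA by camera with a preset correlation, a call lost with an estimated one (adjusted p = 0.104, 0.0757 and 0.0757), and 0 members passed over all genes. Less artery wall with its lesions would lower endothelial and smooth muscle genes as much, but the mean of those scores changed by 0.12 on the log2 scale (exact permutation p = 0.571) and the macrophage score by -1.15, a difference of -1.26. Those scores are not particular to the wall, as the smooth muscle list holds Pln, which heart muscle also expresses. A loss of wall offset by other tissue, or a difference in which part of the aorta was sampled, was therefore not excluded. A response in HFD replicate 4 alone is argued against too, since without it the list medians were -1.20, -1.48 and -2.79. An effect of TUDCA was not tested apart from the structure of the samples that the other splits showed, and stays open.

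UPR genes were higher on HFD and lower with TUDCA. HFD replicate 4 alone is argued against, because without it the list passed camera in both comparisons (medians 0.40 and -0.34, larger adjusted p 2.71e-07, within 1.37e-11 to 0.121 over the alternatives of the TUDCA comparison). More plasma cells could raise ER genes, and within groups the relation of the UPR score to the B cell and plasma cell score over 12 libraries was positive (Pearson r = 0.624, exact permutation p = 0.0526, adjusted over 2 relations 0.105; Spearman rho = 0.678, p = 0.0194, adjusted 0.0388; r = 0.501 without the 2 farthest libraries). They are argued against as the whole cause, since with that trend taken off at either 95% confidence limit of its slope the UPR score still changed by at least 0.449 in both comparisons (exact permutation p = 0.0286 each), and the plasma cell list had a median of -0.01 in HFD+TUDCA vs HFD, but a part stays open. Macrophages cannot be told apart from an effect of diet and TUDCA (r = 0.340, exact permutation p = 0.191; rho = 0.441, p = 0.189; r = -0.0297 without the 2 farthest), because at the upper slope limit the change with TUDCA was 0.211 in size (p = 0.0571).

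Heart muscle genes were lower on HFD as a list by camera with a preset correlation, a call lost with an estimated one (adjusted p = 0.164). Heart tissue left on the aorta in unequal amounts would move these genes together, and 1 factor per library held 83.3% of the variance of the list, where random lists had a median of 53.9% and 44 of 1000 were as high. The factor was taken across the groups, so an effect of diet shared by these genes would raise it too, and it does not decide between them. Of the genes called lower on HFD, 56.0% followed the heart or the epithelial score within groups (r above 0.5), against 28.9% of genes not called and 40.8% of those called higher. These correlations were taken over all 12 libraries. HFD+TUDCA, which is not part of HFD vs NFD, spread most in the heart score (SD 3.35, against 1.11 in HFD and 0.630 in NFD). The same held for the epithelial score (2.04, against 1.20 and 0.421). The shares therefore rest largely on libraries outside the comparison. Carried-over tissue is a candidate explanation for part of the genes called lower. Within HFD+TUDCA the heart score ranged from 0.927 to 9.04, against group means of 7.51 in NFD and 4.88 in HFD. Differences this large thus arose without a difference in diet or treatment. The scores of NFD (6.98 to 8.38) and HFD (3.58 to 6.26) did not overlap. An effect of diet on the heart genes was not tested apart from carried-over tissue.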

How the results depend on the processing

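Tests with a heart or epithelial score as covariate, log2(FPKM + 0.1), DESeq2 with a 2-fold limit, HFD replicate 4 and HFD+TUDCA replicate 4 both left out, and the exact permutation of list scores were chosen after the data were seen. In simulation 2.99% of 2-fold changes were recovered for HFD+TUDCA vs HFD, which limits its count of 0. Why a setting moved a value was not tested. In HFD vs NFD the 720 genes became 1686 with DESeq2, 150 at an adjusted p under 0.01, 377 and 88 with the heart and epithelial covariates (131 and 84 shared), and 178 to 1181 without 1 library. In HFD+TUDCA vs HFD the 0 genes of edgeR became 352 with DESeq2 (243 with the 2-fold limit) and 115 with all 12 libraries in 1 fit, and stayed 0 without any 1 library, with 1745 at an unadjusted p under 0.05. In HFD+TUDCA vs NFD the 29 genes became 533 with DESeq2 (225 with the 2-fold limit), 14 at an adjusted p under 0.01, 50 and 44 on log2(FPKM + 1) and log2(FPKM + 0.1), 137 and 64 with the covariates, and 4 to 682 without 1 library. The replicate block gave 776, 0 and 8 genes and 23, 27 and 16 lists in the 3 comparisons. Same-numbered libraries correlated at 0.0942 to 0.381, -0.465 to -0.234 and -0.359 to -0.0823, with 2, 0 and 0 of 4 pairs each other's best partner. In HFD vs NFD 3 of 4 pairs lay above 0.1, a hint from the data and not the design, and as not every pair did, the numbers were taken not to pair the samples.

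The 24, 27 and 18 lists became 3, 1 and 1 with an estimated correlation, 11, 7 and 3 with fry, and 0, 0 and 0 by exact permutation of scores, where the smallest p is 0.0286 before adjustment. Without 1 library there were 20 to 27, 22 to 29 and 14 to 18. With both HFD replicate 4 and HFD+TUDCA replicate 4 left out of HFD+TUDCA vs HFD, 18 lists passed. Medians or directions then reversed for B cell and plasma cell (0.63), antigen presentation (0.17), cell cycle (-0.23, by its test) and mitochondrially encoded genes (-0.0727). The opposition of -0.720 was -0.852 over genes called in HFD vs NFD, -0.298, -0.263, -0.386, -0.400, -0.254 and -0.350 with the HFD libraries split, and -0.770 to -0.623 without 1 library. Its covariance lay -0.215 from the simulated one, for which genes were drawn independently. Over all alternatives, lists kept direction and side of the threshold in 442 of 532, 431 of 570 and 442 of 532 values, and were weaker in 78, 115 and 80. Named genes did so in 1140 of 1320 values in HFD vs NFD and 465 of 578 in HFD+TUDCA vs NFD, were weaker in 171 and 102, and reversed in 0. In HFD+TUDCA vs HFD no gene was called, so none could become weaker, and 62 of 1154 values became stronger.

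Without 1 library, 23 of 51 named calls of HFD vs NFD were lost in at least 1 of 8 fits (Csf3, Il6, Acod1, Cxcl1, Apoa1, Nppb, Hspa5, Vcam1, Abca1, Pdia4, Manf, Acly, Acaca, Me1, Cyp51, Myh6, Tnnt2, Pln, Cnn1, Ighm, Igkc, Itgb2 and Cyp1a1), as were 18 of 21 in HFD+TUDCA vs NFD, all but Gpnmb, Mmp12 and Sult1a1. No sign changed. Upper-quartile scaling moved the median of all genes by -0.07, 0.00 and -0.03 and turned 0 called lists.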

Other observations

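Nr1h4, which encodes the nuclear bile acid receptor FXR, stood at 1.33 ± 0.776 CPM in NFD, 0.805 ± 0.198 CPM in HFD and 0.213 ± 0.187 CPM in HFD+TUDCA (SD, n = 4), and passed the edgeR test in no comparison (adjusted p = 0.346 in HFD+TUDCA vs HFD). In pathways of the deposited annotation, camera with a preset correlation called 81 lower and 38 higher with TUDCA. Those lower included cytokine-cytokine receptor interaction (adjusted p = 1.20e-11), NF-kappa B signalling (2.66e-10) and IL-17 signalling (8.01e-10), and those higher carbon metabolism (1.22e-09) and the citrate cycle (2.93e-09).

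Genes of tissues next to the aorta, chosen after their values were seen, varied widely within groups. The adrenal gene Cyp11b1 stood at 229, 0.102, 16.9 and 849 CPM in NFD replicates 1 to 4, at 0.184, 1.06, 146 and 545 CPM in HFD, and at 0 to 0.190 CPM in HFD+TUDCA. Star, of steroid synthesis, reached 1736 CPM in NFD replicate 4 and 1141 CPM in HFD replicate 4. The epithelial keratin Krt4 stood at 332 CPM in NFD replicate 4, 309 CPM in HFD replicate 2 and 274 CPM in HFD+TUDCA replicate 3, and at 0.0507 to 2.55 CPM in the other 9 libraries.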
